A study of Capra hircus with 14 samples.

How the data were processed

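RNA from goat (Capra hircus) cells was sequenced in 14 libraries, 2 for each of 7 days of a protocol meant to turn fibroblasts directly into mammary epithelial cells with small molecules. Per the labels' protocols, the day 0 cells, called GEF, were fibroblasts kept in DMEM with fetal bovine serum, and the cells of days 1, 2, 3, 4, 6 and 8 were cultured in a medium called R induction medium, renewed at 2-day intervals. What that medium contains is not given in the sources used here. Ribosomal RNA was removed with a Ribo-Zero Gold kit and libraries were made with a TruSeq kit, per the labels' protocols. Libraries were grouped by the day and the replicate number in their titles.

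The deposited table gives 1 estimated count per gene and library, together with a mean for each day that equals the mean of its 2 libraries and was not used. FastQC 0.10.1, HTSeq and DESeq2 1.16.1 are named in the submitters' processing notes, without their order or settings. The aligner, the genome build, the strand setting and the version of HTSeq are not given in the sources used here. The authors' estimated counts are not all whole: 90.0% of the values, and 83.1% of those above 0, are whole numbers. Counting whole reads with HTSeq would not give fractions, so the step that produced the deposited estimated counts is not known, and it could have split reads between near-identical genes such as KRT5 and KRT6A, KRT14 and the keratin 17 gene, or ACTA2 and ACTG2. Levels of such genes are uncertain for that reason. Overlapping and antisense genes cannot be told apart without the strand setting.

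The table holds 30277 genes, of which 1172 carry identifiers of assembled transcripts. Symbols came from the table for 25219 genes and, through the Entrez identifier, from the RefSeq gene table of assembly ARS1.2 for 3687 more, and 1371 had neither. No coordinates are given because the build is not named. The line of 1 gene held no values and was left out. Estimated counts were rounded to whole numbers before testing.

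Library totals ran from 20515126 to 24746010 estimated counts. A count of 3 in a library, used here as the floor of detection, corresponds to 0.117 to 0.15 CPM (counts scaled to a common library size) depending on the library. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. The spread between libraries of a day exceeded sampling noise on each day, with a chi-square per degree of freedom of 1.8 at day 1 to 8.12 at day 0 over genes with at least 20 counts in the pair, so no library was treated as a copy of another. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The fit shares its estimate of the spread over all days. The day 0 pair differed most, so p-values against day 0 may be too small.

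Genes were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): TMM scaling, filterByExpr over the 7 days, a quasi-likelihood fit of all 14 libraries with a group for each day, and 2-sided quasi-likelihood F tests, with Benjamini-Hochberg adjustment over the 15712 genes tested. A gene was called at an adjusted p under 0.05. The fit had 7 residual degrees of freedom and a common biological coefficient of variation of 0.045. CPM use the TMM-scaled library sizes and are given as mean ± SD, and log2 fold changes with a standard error (SE). The SE was taken as the absolute log2 fold change divided by the square root of F. For large changes where 1 of the days had few counts, it understates the error. With so small a coefficient of variation, many called changes are small, so counts of genes that changed at least 2-fold are given as well. The 12 comparisons were each later day with day 0, each sampled day with the sampled day before it, and day 8 with day 1; an F test over all days was added to these. Between day 0 and day 1 the medium and the time in culture changed together, and no untreated library of a later day was analysed here, so the comparisons with day 0 cannot separate the medium from time in culture. Because the medium was renewed at 2-day intervals, the time since renewal may also have differed between sampled days. It cannot be separated from the day of induction here.

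The tests, the 32 gene lists, the naming rule and the alternatives were fixed before the data were examined, except a comparison of days 1 and 8 with separate day 0 libraries. Lists covered epithelial junctions, luminal and basal epithelium, milk proteins, milk fat, fibroblasts, connective tissue matrix, TGF-beta, contraction, epithelial-mesenchymal transition (EMT), BMP, WNT, cell cycle, cell cycle inhibitors with p53 targets, cholesterol, interferon, inflammation, matrix metalloproteinases, the integrated stress response, heat shock, hypoxia, oxidative phosphorylation, pluripotency, immediate early genes and markers of 8 other cell types (adipocyte, cartilage, stratified skin epithelium, endothelium, leukocyte, Schwann and neural, melanocyte and skeletal muscle). For each list the members called over all genes and those called when p was adjusted over the list alone were counted. Lists with at least 5 tested members were compared with all other genes by camera with a preset correlation of 0.01 and again with an estimated correlation; p was adjusted over the lists and the 6 comparisons with day 0, and separately over the lists and the other 6 comparisons. Terms of GO and KEGG that the deposited table pairs with its genes were tested for over-representation among genes called higher and lower at day 8 by Fisher's exact test (1-sided), for terms of 10 to 500 tested genes, with the tested genes that have a term as background.

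Named genes were, for day 8 against day 0, the 10 with the largest change in each direction among called genes with an average log2 CPM of at least 1 and a symbol that is not a placeholder; for each other comparison, 5 in each direction; for each list, up to 4 members with the smallest p; a fixed set of epithelial, mammary and fibroblast genes whatever their values; and, for terms, the 4 called members with the largest change. Some genes that the rule takes are not reported here. Against a day with 0 counts the fold is given as a lower bound, set by 3 counts over both libraries of that day. With 1 to 3 counts the ratio of counts is given with its 95% interval, for counting error only.

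The steps were tested on simulated counts made from the day 0 means for all libraries, with 200 genes among 15712 changed at day 8. In the deposited data 70.9% of the tested genes were called at day 8. Scaling and calling where most genes change were therefore not covered by these simulations. For day 8 against day 0, 79.1% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 97.0% of those changed 4-fold were recovered. In that test 18 unchanged genes were called, 9.3% of the calls, which is above the nominal level. Camera and the term test called none of the random sets and called the raised one, and the overlap step found 28 of 30 planted genes.

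Alternatives were DESeq2 size factors, the DESeq2 1.42.0 test, no filter, a filter of CPM of at least 1 in 2 libraries, the replicate number as a block, a fit of the libraries of the compared days alone, each library left out in turn, a test against a 1.5-fold change (glmTreat), fry for lists, terms from genes changed at least 2-fold, and principal components of all tested genes. Groups of 2 libraries are too small for a search for outlying libraries or for regrouping of samples, and neither was done. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.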

Results

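Gene expression was measured in goat fibroblasts (day 0) and in the same kind of cells after 1, 2, 3, 4, 6 and 8 days in R induction medium, with 2 libraries per day. Totals were 20515126 to 24746010 estimated counts per library, and 15712 genes were tested. Libraries of the same day were closest to each other, with Spearman correlations over genes of 0.995 to 0.997 in 7 pairs, against 0.898 to 0.984 in the 84 pairs from different days. The first principal component of the 500 most variable genes held 65.8% of the variance and ordered the days from day 0 to day 8, and the second held 21.3%. Mitochondrially encoded genes took 2.9% to 4.16% of the counts, ribosomal protein genes 3.61% to 6.28%, and the 10 most counted genes 6.7% to 9.5%. Between any of the 7 days, 14520 genes (92.4%) differed by the edgeR F test.

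**Figure D1:**
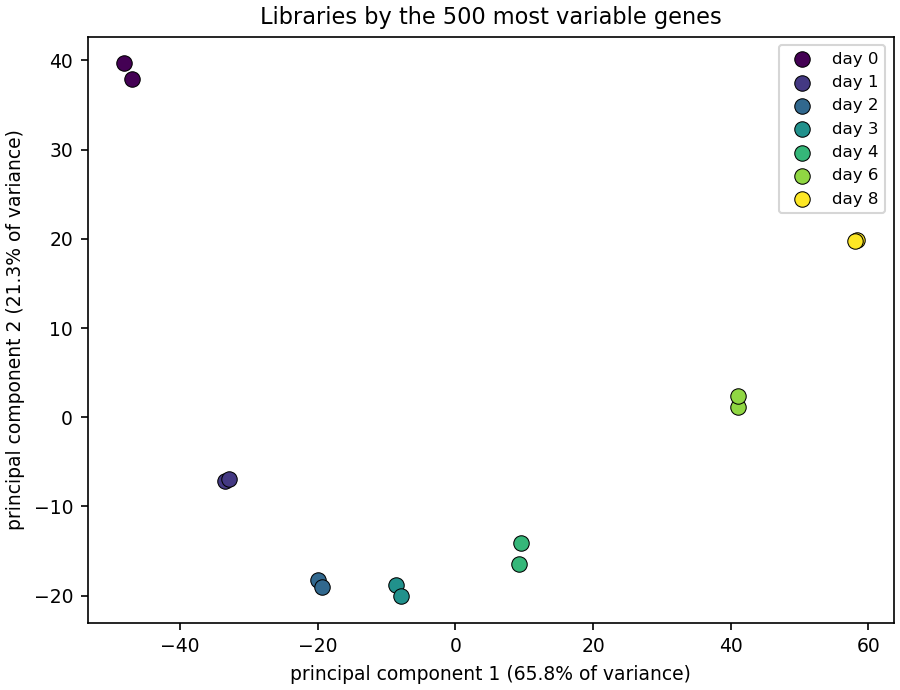
Principal components of log2 CPM over the 500 most variable tested genes, 1 point per library and 1 colour per day. The first component (65.8% of the variance) orders the days and the second (21.3%) separates days 0 and 8 from the days between them.

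The cells at day 0 already held transcripts of epithelial genes beside those of fibroblasts. KRT5 and KRT14, keratins of basal epithelial cells, stood at 3810 ± 274 and 4388 ± 338 CPM (SD, n = 2), KRT8, a keratin of simple epithelia, at 1910 ± 109 CPM, and the adhesion genes CDH1 (E-cadherin) and EPCAM at 110.1 ± 2.98 and 81.35 ± 2.53 CPM. In the same libraries VIM (vimentin) was at 8823 ± 28.3 CPM and COL1A1 (type I collagen) at 9573 ± 716 CPM.

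Day 8 was compared with day 0 to see how the cells at the end of induction differed from the starting fibroblasts. Basal epithelial genes were higher at day 8: KRT5 reached 25370 ± 418 CPM (SD, n = 2) from 3810 ± 274 CPM, a log2 fold change of 2.73 ± 0.0475 (SE; adjusted p = 6.98e-24), KRT6A rose by 3.21 ± 0.0526, KRT14 by 1.73 ± 0.0489 and TP63, the transcription factor p63 that maintains basal epithelium, by 2.85 ± 0.0564. Of 13 tested members of the basal list, 9 were higher, 3 lower and 1 was not called, with a median log2 fold change of 1.02 (camera adjusted p = 1.87e-07; adjusted p = 0.0529 with an estimated correlation, so the call was lost). Among 32 epithelial junction genes, 21 were higher, 7 lower and 4 not called, with a median of 0.95 (adjusted p = 3.57e-05, and 0.0352 with an estimated correlation). DSP, the desmosomal protein desmoplakin, rose by 3.25 ± 0.0554, PKP1 (plakophilin 1) by 2.49 ± 0.0568 and EHF, an epithelial transcription factor, by 2.62 ± 0.0762. CDH1 rose by 0.97 ± 0.0589 to 215.5 ± 4.79 CPM. EPCAM was called higher by 0.17 ± 0.0707 (adjusted p = 0.031), a call that was lost without day 0 replicate 1 (adjusted p = 0.121), without day 8 replicate 2 (0.247) and in the fit of days 0 and 8 alone (0.0526). Log2 fold changes are given ± SE from the fit of all 14 libraries, 2 per day. The SE therefore does not measure the spread of the compared days alone. KRT5 and KRT6A, or KRT14 and the keratin 17 gene, may share reads, and no untreated library of day 8 was analysed here, so the medium and time in culture cannot be separated.

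Luminal genes split. KRT8 fell by 3.49 ± 0.0507 to 169.9 ± 0.545 CPM and KRT18, its partner in simple epithelia, by 6.64 ± 0.0998 to 1.573 ± 0.21 CPM, while KRT7 rose by 2.06 ± 0.0581 and KRT19 by 1.11 ± 0.0499. TFAP2C rose by 3.49 ± 0.114 and GATA3, a regulator of luminal cells, by 1.94 ± 0.149. ELF5, a regulator of the secretory mammary lineage, rose by 4.72 ± 0.43 (adjusted p = 7.16e-10), from 0.1872 CPM (7 and 1 counts in the 2 libraries) to 5.059 CPM. The rise of ELF5 was 6.60 without day 0 replicate 1 and 3.95 without day 0 replicate 2. ESR1, the estrogen receptor, was at 0.2887 CPM against 0.5127 CPM (adjusted p = 0.251). In the luminal list of 17 tested genes, 9 were higher, 5 lower and 3 not called, with a median of 1.11 (adjusted p = 0.683). Other members of that list had too few counts on all days to be tested. FOXA1, PGR and KIT had at most 10, 7 and 5 counts in a library, and SPDEF, ERBB4 and TNFSF11 at most 4, 1 and 1. STAT5A was not found by symbol.

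Of the milk protein list, caseins and most others were at or near the detection floor. CSN2, CSN1S1, CSN1S2, LALBA, PAEP and GLYCAM1 had 0 counts in each of the 14 libraries, CSN3 had 1 count in all of them together, and LTF had at most 8 counts in a library. In a single library a level of up to 0.117 to 0.15 CPM would not have been detectable at this depth. For the genes with 0 counts in all 14 libraries together the limit is lower. The 2 tested members of the list were SPP1, which fell by 3.66 ± 0.0777, and LPO, which was at 1.058 CPM against 1.865 CPM (adjusted p = 0.0581). LPO passed when adjusted over the list alone (0 higher and 2 lower members), in the fit of days 0 and 8 alone (adjusted p = 0.0371), with the stricter filter (0.047) and without day 6 replicate 2 (0.0492). Of 20 tested genes of milk fat synthesis and secretion, 10 were higher, 5 lower and 5 not called, with a median of 0.42 (adjusted p = 0.173). Not tested from that list were BTN1A1, with 0 counts in each of the 14 libraries, and THRSP, with at most 4 counts in a library. In that list PLIN2, a coat protein of lipid droplets, rose by 3.97 ± 0.059 and GPAM, an enzyme of triglyceride synthesis, by 1.80 ± 0.0895, and MFGE8 fell by 1.72 ± 0.0601.

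Fibroblast and matrix genes were lower. VIM fell by 1.40 ± 0.0402 but was still at 3349 ± 54.1 CPM, S100A4 fell by 3.20 ± 0.063, CD248 by 3.20 ± 0.0876 and PDGFRB by 2.25 ± 0.0617. Of 22 fibroblast genes 15 were lower, 6 higher and 1 was not called, with a median of -1.31 (adjusted p = 1.36e-06, and 0.00797 with an estimated correlation). In the list of collagens and connective tissue matrix, 15 of 21 genes were lower and 5 higher, with a median of -0.71 (adjusted p = 7.21e-05, but adjusted p = 0.185 with an estimated correlation, so the call was lost). BGN (biglycan) fell by 3.58 ± 0.0569 and COL6A2 by 2.95 ± 0.0588, FN1 (fibronectin) by 1.37 ± 0.0615, COL1A1 by 0.88 ± 0.0518 and COL1A2 by 0.27 ± 0.0413. Matrix metalloproteinases and their inhibitors fell in 17 of 18 cases, with a median of -2.03 (adjusted p = 8.37e-21, and 0.00308 with an estimated correlation). MMP13 fell by 6.94 ± 0.113 and TIMP1 by 4.03 ± 0.0612.

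TGF-beta responsive genes and contractile genes went in opposite directions. IL11 fell by 8.37 ± 0.149 and SMAD7, an inhibitor induced by TGF-beta signalling, fell by 2.91 ± 0.103, whereas IGFBP3 rose by 3.11 ± 0.0452. All 23 tested members of the TGF-beta list were called, 17 lower and 6 higher, with a median of -0.75 (adjusted p = 0.000183, and 0.0185 with an estimated correlation). Contractile genes were higher in 12 of 14 cases and lower in 2, with a median of 2.32 (adjusted p = 2.6e-26, and 0.00109 with an estimated correlation). MYLK (myosin light chain kinase) rose by 6.45 ± 0.071, MYH11 (smooth muscle myosin) by 5.22 ± 0.0669, ACTA2 (smooth muscle actin) by 3.55 ± 0.0502 and ACTG2, which may share reads with ACTA2, by 4.59 ± 0.0753. TAGLN was called higher by 0.12 ± 0.0474 (adjusted p = 0.0223), a call lost in the fit of days 0 and 8 alone (adjusted p = 0.105) and without day 0 replicate 2 (0.103) or day 8 replicate 1 (0.0538) or 2 (0.12). Of 10 EMT genes 6 were lower and 4 not called, with a median of -0.77 (adjusted p = 0.016, but adjusted p = 0.068 with an estimated correlation, so the call was lost). CDH2 (N-cadherin) fell by 2.14 ± 0.0753, SNAI1 by 2.60 ± 0.12, TWIST1 by 0.90 ± 0.0921 and ZEB1 by 0.73 ± 0.111, while SNAI2 had a log2 fold change of 0.12 (adjusted p = 0.109) and ZEB2 of 0.00 (adjusted p = 0.991, with -0.11 without day 0 replicate 1 and 0.14 without day 0 replicate 2, neither called, adjusted p = 0.276 and 0.154). SNAI2 was called higher without day 0 replicate 2 (0.23, adjusted p = 0.00464), day 3 replicate 1 (0.0455) or day 6 replicate 1 (0.049).

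Inflammatory and immediate early genes were lower. LIF fell by 6.71 ± 0.0969, IL6 by 5.55 ± 0.102 and CXCL8 by 5.18 ± 0.0908, and of 16 inflammatory genes 12 were lower, 2 higher and 2 not called, with a median of -1.88 (adjusted p = 3.4e-12, and 0.00808 with an estimated correlation). Of 20 immediate early genes, 15 were lower and 3 higher, with a median of -1.3 (adjusted p = 6.17e-07, but adjusted p = 0.0561 with an estimated correlation, so the call was lost), among them SPRY4, which fell by 6.24 ± 0.186, and EGR1, by 2.72 ± 0.0829. Interferon response genes were lower in 13 of 17 cases and higher in 3, with a median of -0.85 (adjusted p = 0.0242, but adjusted p = 0.0724 with an estimated correlation, so the call was lost). IFI6 fell by 2.31 ± 0.0771 and MX2 rose by 1.82 ± 0.17. Hypoxia and glycolysis genes were lower in 14 of 20 cases and higher in 4, with a median of -0.83 (adjusted p = 0.00162, and 0.0308 with an estimated correlation). VEGFA fell by 3.42 ± 0.0605 and NDRG1 by 2.33 ± 0.0549, and SLC2A1, a glucose transporter, rose by 1.37 ± 0.0456.

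The lists of this paragraph were not called at day 8. Of 30 cell cycle genes 21 were lower and 6 higher, with a median of -0.23 (adjusted p = 0.199). CDC20 fell by 0.79 ± 0.0593 and E2F1 by 1.19 ± 0.102, and MKI67, a marker of proliferation, rose by 0.58 ± 0.065. Of 15 cell cycle inhibitors and p53 targets 9 were higher and 4 lower, with a median of 0.59 (adjusted p = 0.132), with CDKN1A (p21) higher by 0.59 ± 0.048 and SESN1 by 2.50 ± 0.135. In the BMP and ID list of 14 genes 6 were higher and 4 lower, and its median (0.09), mean (-0.19) and test (down, adjusted p = 0.682) differed in sign. HEY1 fell by 3.27 ± 0.144. WNT genes were higher in 7 of 13 cases and lower in 5, with a median of 0.83 (adjusted p = 0.118). SFRP1 rose by 2.54 ± 0.0622, WIF1 fell by 3.84 ± 0.154, and NKD1 had 1217 counts against 1 count, a ratio of 1180 (95% interval 211 to 46600). Cholesterol synthesis genes were higher in 7 of 20 cases and lower in 9, with a median of -0.04, a mean of 0.05 and a test in the direction of the mean (adjusted p = 0.684). TM7SF2 rose by 3.67 ± 0.0693. In the integrated stress response list of 18 genes, 8 were higher and 9 lower, with a median of -0.19 against a mean of 0.39 and a test in the direction of the mean (adjusted p = 0.216). PSAT1 and PHGDH, enzymes of serine synthesis, rose by 2.73 ± 0.0521 and 1.49 ± 0.0557.

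Heat shock genes were higher in 4 of 11 cases and lower in 6, with a median of -0.2 (adjusted p = 0.85). HSPB1 rose by 0.67 ± 0.0624. Of 13 nuclear genes of oxidative phosphorylation 8 were higher and 1 lower, with a median of 0.22 (adjusted p = 0.488). ATP5A1 rose by 0.69 ± 0.0463. The pluripotency list had 3 tested members and no camera test: TFCP2L1, which rose by 6.61 ± 0.121, KLF4, which rose by 0.90 ± 0.0744, and KLF2, which fell by 3.35 ± 0.221. Its members POU5F1, LIN28B, DPPA4, ZFP42, TDGF1 and PRDM14 had 0 counts in each of the 14 libraries. SOX2, SALL4, UTF1 and ESRRB had at most 15, 9, 1 and 5 counts in a library. NANOG, LIN28A and DPPA3 were not found by symbol.

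Markers of other cell types were examined in the same comparison. Genes of stratified skin epithelium were higher in 11 of 12 cases with 1 not called, with a median of 5.18 (adjusted p = 1.77e-24, and 0.000521 with an estimated correlation). KRT1, a keratin of differentiating epidermis, rose by 10.39 from 4 counts at day 0 to 132.5 ± 2.67 CPM, a fold left uncertain by so few counts. SBSN rose by 5.76 ± 0.0962, DSG1 by 5.26 ± 0.0944 and IVL (involucrin) by 4.59 ± 0.0801. Leukocyte markers were lower in 4 of 5 cases with 1 not called, with a median of -3.06 (adjusted p = 0.00244, and 0.0405 with an estimated correlation), including CD14, which fell by 3.95 ± 0.0814. Of 5 Schwann and neural markers 3 were lower and 1 higher, with a median of -1.61 (adjusted p = 0.000449, and 0.0275 with an estimated correlation). STMN2 fell by 5.03 ± 0.123. Endothelial markers were lower in 5 of 7 cases and higher in 1, with a median of -2.06 (adjusted p = 0.123). EGFL7 fell by 2.78 ± 0.125. Adipocyte markers were higher in 6 of 12 cases and lower in 4, with a median of 0.7 (adjusted p = 0.406). CEBPA rose by 3.43 ± 0.121 and CIDEC fell by 4.54 ± 0.389. Cartilage markers were higher in 5 of 9 cases and lower in 3, with a median of 0.42 (adjusted p = 0.778). ACAN rose by 2.02 ± 0.134 and SOX9 fell by 1.60 ± 0.0697. Of 5 skeletal muscle markers 2 were higher and 3 lower, with a median of -1.56, a mean of 0.28 and a test in the direction of the mean (adjusted p = 0.637); ACTC1, a striated muscle actin, rose by 6.96 ± 0.355. The 3 tested melanocyte markers had no camera test, with 1 higher (MITF, by 0.36 ± 0.11), 1 lower (PMEL, by 0.68 ± 0.194) and 1 not called, a median of 0.2 and a mean of -0.04.

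Adjusted over the list alone, the counts at day 8 were the same as over all genes except for the milk proteins (0 higher and 2 lower), WNT genes (7 and 6), cell cycle genes (6 and 22) and hypoxia and glycolysis genes (5 and 14). Across all genes 5651 were higher and 5496 lower, 70.9% of those tested, of which 2530 and 2000 changed at least 2-fold and 1239 and 836 at least 4-fold. Several of the genes named for their rise had 0 counts at day 0. Of these, C28H10orf99 was at least 513-fold higher (1589 against 0 counts), ADTRP at least 194-fold, PLIN4, a lipid droplet protein, at least 191-fold, ENDOU at least 181-fold, TNN at least 158-fold, MYOC at least 144-fold and SBSPON at least 104-fold, each against a floor of 3 counts over both day 0 libraries. MATN2 and ATP6V1B1 had 1 count at day 0, with ratios of 1440 (95% interval 259 to 57100) and 1180 (212 to 46700). Under the abundance and symbol limits of the rule for named genes, falls beside IL11 included VGF, which fell by 10.08 ± 0.127 from 666.3 to 0.6122 CPM, C1QL2, which fell by 9.16 ± 0.161, ESM1, which fell by 8.53 ± 0.11, GDF10, which fell by 8.24 ± 0.221, MMP9, which fell by 8.16 ± 0.242, and RASGRF1, which fell by 7.07 ± 0.145. CALY (ratio 330, interval 91.1 to 2730), TAC1 (257, 87.6 to 1250) and SRPX2 (245, 67.4 to 2030) were lower, with 2 to 3 counts left at day 8.

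**Figure D2:**
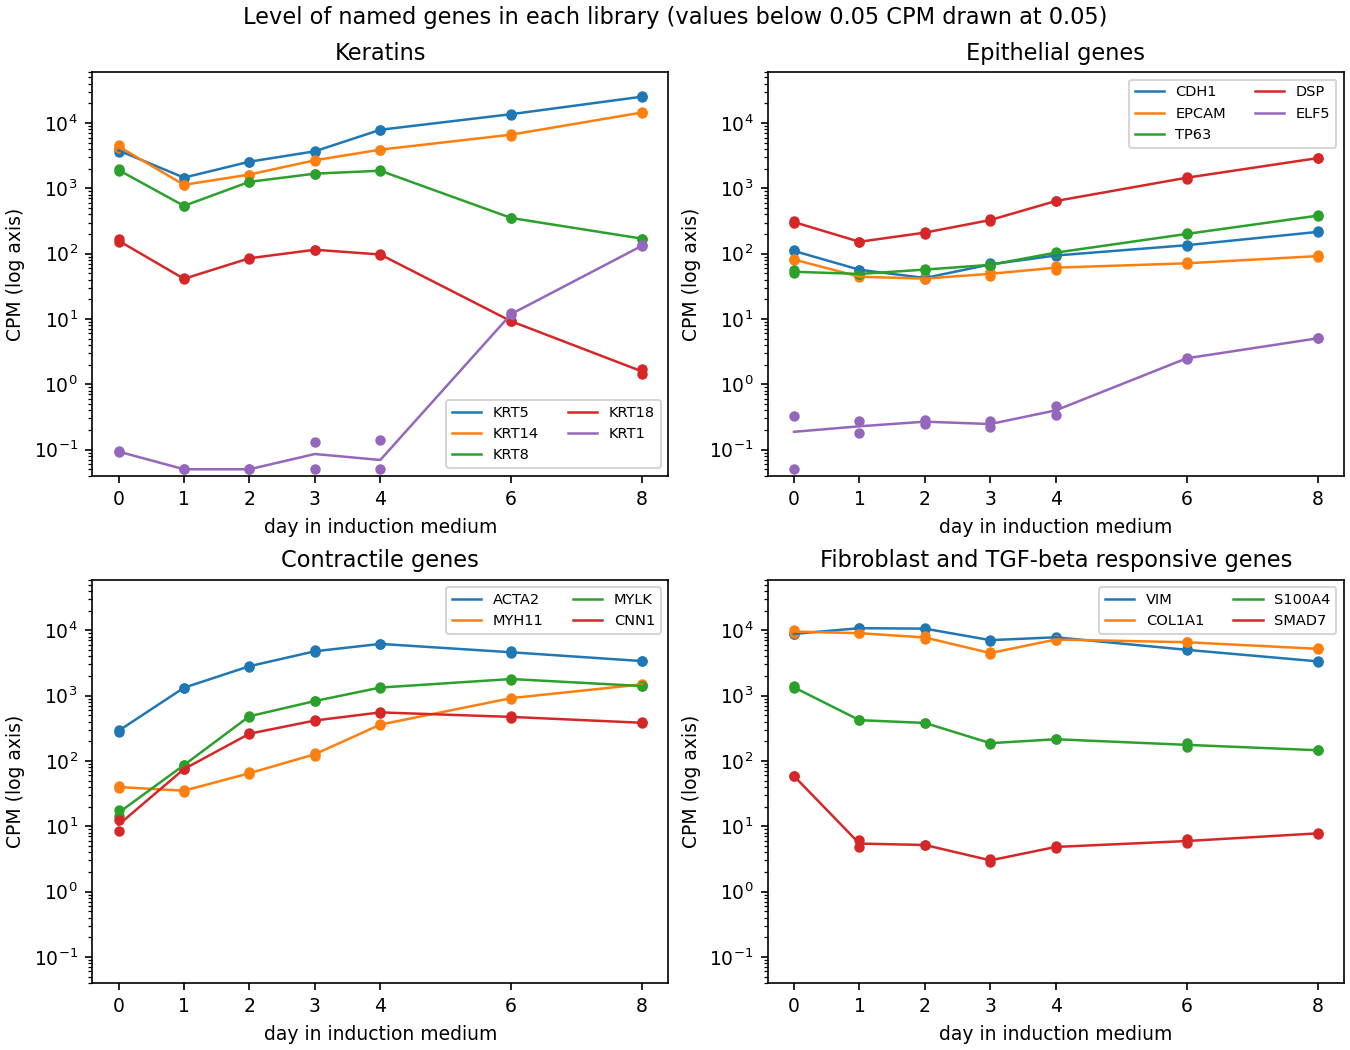
CPM (log axis) of epithelial, fibroblast and contractile marker genes by day, with points for the 2 libraries, lines for their mean, and values under 0.05 CPM drawn at 0.05. KRT5 rises to 25370 CPM at day 8 after a minimum of 1461 CPM at day 1, while KRT18 ends at 1.573 CPM.

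Among 2571 terms tested at day 8, 26 were over-represented in genes called higher and 46 in genes called lower by Fisher's exact test. Genes of retinol metabolism were higher in 24 of 29 cases (adjusted p = 0.000818), linoleic acid metabolism in 18 of 20 (0.000987), keratin filament in 20 of 24 (0.0015), drug metabolism by cytochrome P450 in 27 of 37 (0.00209), keratinocyte differentiation in 23 of 33 (0.0202), fatty acid beta-oxidation in 18 of 24 (0.0215) and establishment of the skin barrier in 11 of 13 (0.0404). LOC102174170, described as a glutathione S-transferase A1, had 17114 counts at day 8 and 1 at day 0, a ratio of 16600 (95% interval 2970 to 655000). KRT2 was at least 159-fold higher. Genes called lower made up 14 of 14 genes of collagen catabolism (adjusted p = 0.000987), 75 of 127 lysosome genes (0.00105), 50 of 82 heparin binding genes (0.00209), 57 of 105 genes of TNF signalling (0.0448) and 35 of 47 proteasome genes (0.000818). The proteasome term was no longer called among genes changed at least 2-fold (adjusted p = 1), nor was fatty acid beta-oxidation (0.137). CTSK (cathepsin K) fell by 3.75 on the log2 scale, and CSF2 was at least 76.1-fold lower.

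Day 1 was compared with day 0 for the early response. Epithelial transcripts fell within 1 day: KRT14 by 1.95 ± 0.0494 to 1133 ± 9.65 CPM (SD, n = 2), KRT5 by 1.38 ± 0.0455 to 1461 ± 4.95 CPM, KRT8 by 1.82 ± 0.0469, KRT19 by 2.07 ± 0.055, CDH1 by 0.96 ± 0.0631 and EPCAM by 0.88 ± 0.0748, while TP63 had a log2 fold change of -0.11 (adjusted p = 0.106). TP63 was called lower with DESeq2 size factors (adjusted p = 0.0314), with DESeq2 (0.0455) and without day 0 replicate 1 (-0.18, 0.0127). Of 13 basal genes 12 were lower and 1 not called, with a median of -0.99 (adjusted p = 4.75e-12, and 0.0185 with an estimated correlation). Of 32 junction genes 23 were lower and 4 higher, with a median of -0.89 (8.96e-05 and 0.0434, where paired values are adjusted p with the preset and with an estimated correlation, here and in later comparisons). Of 17 luminal genes 10 were lower and 4 higher, with a median of -0.76 (0.000206 and 0.0185). BMP and ID genes were lower in 12 of 14 cases and higher in 1, with a median of -1.38 (adjusted p = 2.81e-08, and 0.0326 with an estimated correlation). ID1, a target of BMP signalling, fell by 4.03 ± 0.1. Of 23 TGF-beta responsive genes 15 were lower and 5 higher, with a median of -0.77 (1.11e-07 and 0.00604). SMAD7 fell by 3.44 ± 0.109 and PMEPA1 fell by 3.40 ± 0.0904. Contractile genes were higher in 10 of 14 cases and lower in 2, with a median of 0.99 (2.13e-09 and 0.00915). ACTA2 rose by 2.19 ± 0.0478 and LMOD1 by 3.18 ± 0.0981.

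Matrix, stress and metabolic genes also moved at day 1. Collagen and matrix genes were higher in 15 of 21 cases and lower in 5, with a median of 0.62 (adjusted p = 4.17e-05, but adjusted p = 0.185 with an estimated correlation, so the call was lost). THBS1 (thrombospondin 1) rose by 2.02 ± 0.0671 to 12230 CPM and VCAN by 1.89 ± 0.0693, while COL1A1 had a log2 fold change of -0.08 (adjusted p = 0.154). COL1A1 was called lower with DESeq2 size factors (-0.12, adjusted p = 0.0446) and without day 0 replicate 2 (-0.16, 0.00609). Integrated stress response genes were higher in 11 of 18 cases and lower in 5, with a median of 0.46 (4.91e-06, and 0.0434 with an estimated correlation). SLC7A11, the cystine transporter, rose by 6.08 ± 0.166, PSAT1 by 2.21 ± 0.0517 and ASNS by 1.72 ± 0.0568. Cholesterol synthesis genes were lower in 16 of 20 cases and higher in 0, with a median of -0.66 (0.00028 and 0.0185). Metalloproteinase genes were lower in 15 of 18 and higher in 2 (median -0.78, 1.2e-09 and 0.00974). Hypoxia and glycolysis genes were lower in 15 of 20 and higher in 3 (median -0.72, 0.000434 and 0.0202). Called by camera with the preset correlation alone were immediate early genes (4 higher and 12 lower, adjusted p = 0.0568 with an estimated correlation), oxidative phosphorylation (0 and 11, 0.381), heat shock (1 and 9, 0.149), interferon response (2 and 11, 0.0987) and Schwann and neural markers (1 and 4, 0.0604). Fibroblast genes went both ways, with 10 higher and 9 lower of 22 (adjusted p = 0.218), PDGFRA higher by 1.58 ± 0.0611 and S100A4 lower, at 421.1 against 1337 CPM. Adjusted over the list alone the counts for the lists given here were the same, except 0 and 12 for oxidative phosphorylation and 4 and 13 for immediate early genes.

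Across all genes 5474 were higher and 5428 lower at day 1, of which 2208 and 1477 changed at least 2-fold. ZBTB16, a zinc finger transcription factor, was at least 120-fold higher (370 against 0 counts), SLC16A9 at least 22.3-fold and PLIN4 at least 9.06-fold. RSPO2 had a ratio of 129 (95% interval 35.2 to 1070). SDPR rose by 6.65 ± 0.28. Large falls were in TAC1, which fell by 7.20 ± 0.319, MMP13, which fell by 6.94 ± 0.113, EEF1A2, which fell by 6.26 ± 0.151, and CD24, which fell by 4.79 ± 0.373.

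At day 2 the contractile genes had risen further and the cell cycle genes were lower than at day 0. MYLK stood 4.91 ± 0.0688 and CNN1 (calponin) 4.63 ± 0.091 higher on the log2 scale, and 12 of 14 contractile genes were higher and 1 lower, with a median of 1.62 (adjusted p = 3.01e-31; 0.000599 with an estimated correlation). Of 30 cell cycle genes 24 were lower and 1 higher, with a median of -0.59 (6.15e-06 and 0.00841). CDC20 fell by 1.48 ± 0.0618 from 200.9 to 72.1 CPM. Cell cycle inhibitors and p53 targets were higher in 11 of 15 cases and lower in 3, with a median of 0.64 (0.000669 and 0.0258). CCNG1 rose by 1.33 ± 0.054. Junction genes were lower in 23 of 32 cases and higher in 4, with a median of -0.93 (4.22e-05 and 0.0387). CDH1 was at its minimum among the sampled days, 42.43 ± 2.57 CPM. Leukocyte markers were lower in 4 of 5 cases and higher in 1, with a median of -1.46 (0.00897, but adjusted p = 0.0587 with an estimated correlation, so the call was lost). Basal genes were lower in 9 of 13 cases and higher in 2 (3.44e-06, but adjusted p = 0.0587 with an estimated correlation, so the call was lost), with KRT5 at 2562 ± 24.3 CPM. Adjusted over the list alone, these counts were the same. In all 5167 genes were higher and 4970 lower, of which 1896 and 1263 changed at least 2-fold. ZBTB16 was at least 275-fold, PLIN4 at least 52.9-fold and MYOC at least 33.1-fold higher, SDPR rose by 9.75 ± 0.193, and MMP13 fell by 7.55 ± 0.123 and LRRC32 fell by 6.72 ± 0.183.

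At day 3 cell cycle inhibitors and p53 targets had their highest median among the sampled days. CDKN1A rose by 1.71 ± 0.0481 to 491.4 CPM, MDM2 by 2.03 ± 0.066 and ZMAT3 by 2.11 ± 0.0952, and of 15 cell cycle inhibitors and p53 targets 12 were higher and 3 lower, with a median of 0.95 (adjusted p = 1.24e-05, and 0.0113 with an estimated correlation). Contractile genes were higher in 12 of 14 cases and lower in 1, with a median of 1.89 (1.21e-36 and 0.000521). ACTA2 rose by 4.05 ± 0.0513. Cartilage markers were higher in 7 of 9 cases and lower in 1, with a median of 1.42 (0.0358, but adjusted p = 0.0987 with an estimated correlation, so the call was lost), including ACAN, by 2.46 ± 0.128. Fibroblast genes were lower in 14 of 22 cases and higher in 5 (median -0.29, 0.0257, but adjusted p = 0.0703 with an estimated correlation, so the call was lost). S100A4 fell by 2.84 ± 0.0616. Leukocyte markers were lower in 4 of 5 cases and higher in 0 (4 and 1 adjusted over the list alone), with a median of -0.97 (0.00909, but adjusted p = 0.0587 with an estimated correlation, so the call was lost). KRT5 was at 3698 ± 106 CPM (log2 fold change -0.04, adjusted p = 0.396). Its value depended on the day 0 library kept, at -0.11 without day 0 replicate 2 (adjusted p = 0.0106, called lower) and 0.03 without day 0 replicate 1 (0.492). KRT14 was lower, by -0.70 ± 0.0478. Adjusted over the list alone, the counts of the other lists given here were the same. In all 5637 genes were higher and 5506 lower, of which 2421 and 1661 changed at least 2-fold. ZBTB16 was at least 180-fold, PLIN4 at least 116-fold and SLC16A9 at least 61.8-fold higher. MMP13 fell by 10.07 from 183.6 to 0.1634 CPM, a fold left uncertain by the low level at day 3.

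At day 4 KRT5 exceeded its day 0 level and the contractile genes were at their highest median among the sampled days. KRT5 rose by 1.05 ± 0.045 to 7892 ± 108 CPM (SD, n = 2), TP63 by 0.97 ± 0.0572, KRT7 by 1.01 ± 0.0576 and KRT19 by 1.06 ± 0.0499, while KRT14 was called lower by -0.16 on the log2 scale (adjusted p = 0.00406). Without day 0 replicate 1 that call was lost (-0.08, adjusted p = 0.0999). KRT8 was at 1863 ± 46 CPM (adjusted p = 0.491), and was called lower without day 0 replicate 2 (-0.11, adjusted p = 0.0263). Of 14 contractile genes 12 were higher and 0 lower, with a median of 2.5 (adjusted p = 7.2e-51, and 0.000521 with an estimated correlation). ACTA2 reached 6194 ± 29.8 CPM and MYLK rose by 6.37 ± 0.0709. Basal genes were higher in 6 of 13 cases and lower in 4 (median 0.12, adjusted p = 0.945, with a test in the direction down). Junction genes were higher in 9 of 32 and lower in 16 (median -0.32, 0.379). Cell cycle genes were lower in 28 of 30 cases and higher in 0, with a median of -0.64 (5.48e-07 and 0.00651). FOXM1 stood at 16.04 against 42.18 CPM. Leukocyte markers were lower in 4 of 5 cases and higher in 0, with a median of -1.38 (0.00353 and 0.0434). Adjusted over the list alone, these counts were the same. In all 5334 genes were higher and 5264 lower, of which 2297 and 1388 changed at least 2-fold. PLIN4 was at least 363-fold, ZBTB16 at least 217-fold and MYOC at least 67.3-fold higher, and MMP13 fell by 8.39 ± 0.133.

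Day 6 brought higher markers of stratified epithelium and lower KRT8 and KRT18. DSG1 rose by 4.17 ± 0.0964, SBSN by 3.70 ± 0.104 and IVL by 3.39 ± 0.0822, and of 12 skin markers 10 were higher and 1 lower, with a median of 3.06 (adjusted p = 8e-10, and 0.00457 with an estimated correlation). KRT18 fell by 4.10 ± 0.075 to 9.226 ± 0.0158 CPM and KRT8 by 2.44 ± 0.0481, while KRT5 rose by 1.84 ± 0.0459 and TP63 by 1.92 ± 0.0562. Basal genes were higher in 9 of 13 cases and lower in 4, with a median of 0.56 (0.0281, but adjusted p = 0.314 with an estimated correlation, so the call was lost). Junction genes were higher in 17 of 32 and lower in 11 (0.0722). Contractile genes were higher in 12 of 14 cases and lower in 1, with a median of 2.34 (6.37e-35 and 0.000521). Fibroblast genes were lower in 15 of 22 and higher in 6, with a median of -0.91 (0.00145 and 0.0289). Inflammatory genes were lower in 13 of 16 and higher in 2, with a median of -1.5 (3.34e-12 and 0.00604). Leukocyte markers were also lower in 4 of 5 cases and higher in 1, with a median of -2.61 (0.00459 and 0.0481). Schwann and neural markers were lower in 4 of 5 cases and higher in 0, with a median of -0.51 (0.00299 and 0.0432). CD14 fell by 3.89 ± 0.081 and STMN2 fell by 4.29 ± 0.112. ASPN rose by 6.39 ± 0.13 and LIF fell by 6.28 ± 0.0927. Adjusted over the list alone, these counts were the same. In all 5959 genes were higher and 5888 lower, of which 3046 and 1915 changed at least 2-fold, with PLIN4 at least 301-fold and C28H10orf99 at least 199-fold higher and TAC1 at least 255-fold lower.

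**Figure D3:**
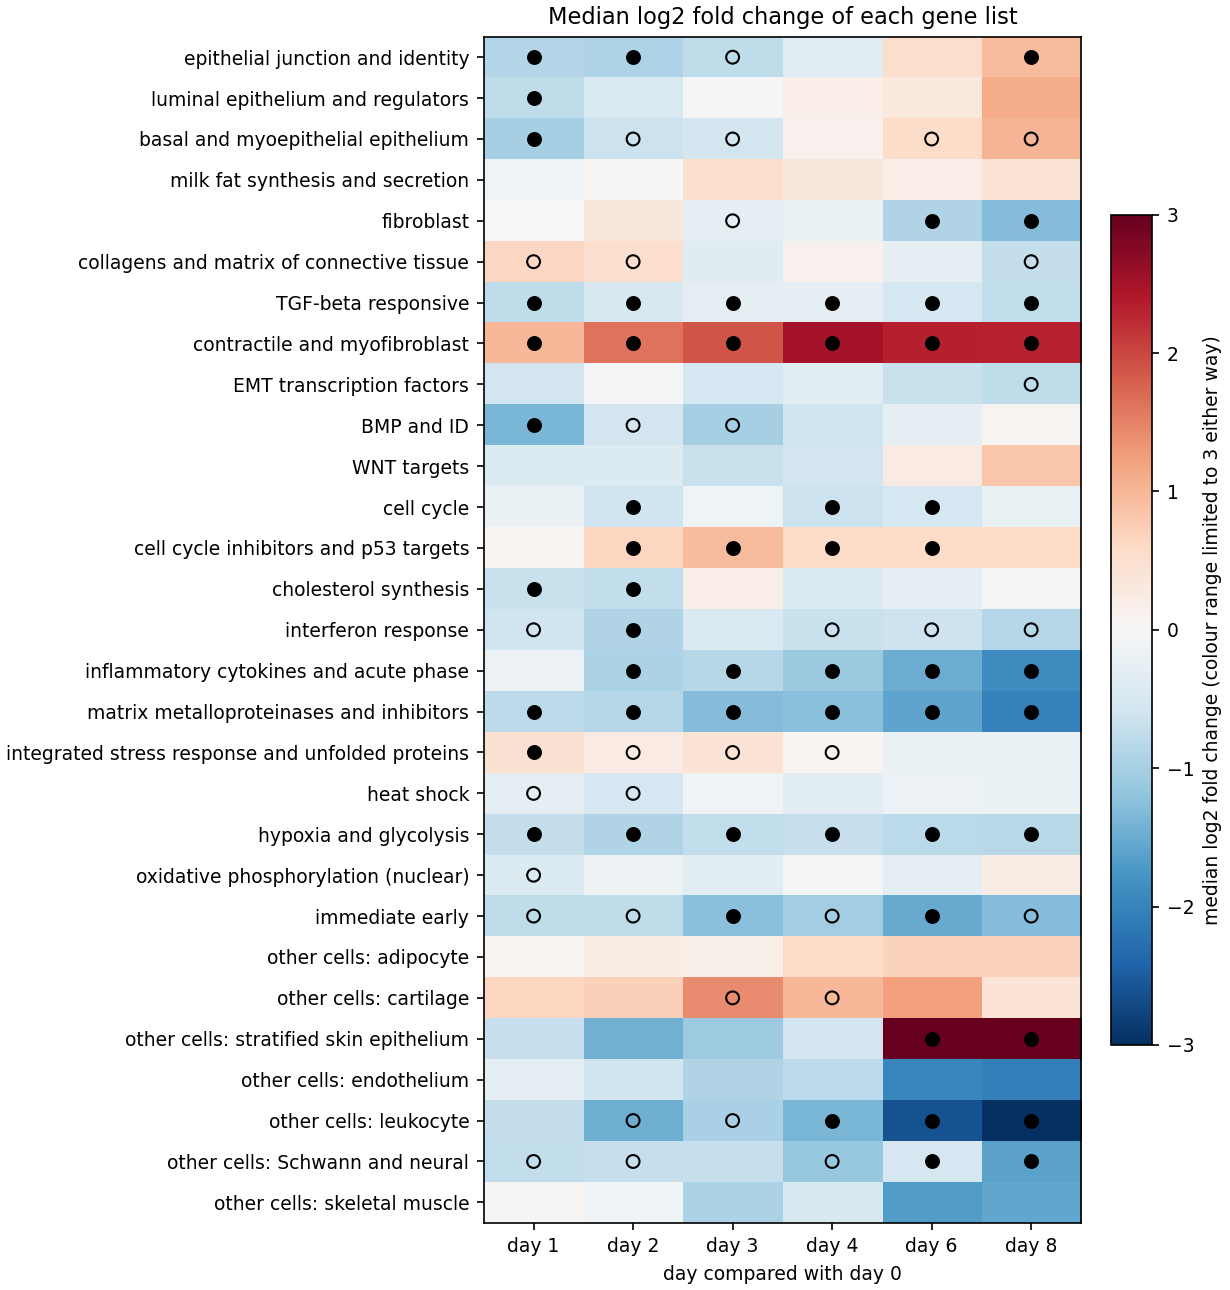
Median log2 fold change against day 0 of each gene list with at least 5 tested members (29 lists), by day, with colours limited to 3 in either direction; circles mark lists called by camera with the preset correlation, filled where the call held with an estimated correlation. The contractile list is called higher on each day, with medians of 0.99 at day 1 and 2.32 at day 8, and the skin list from day 6.

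**Figure D4:**
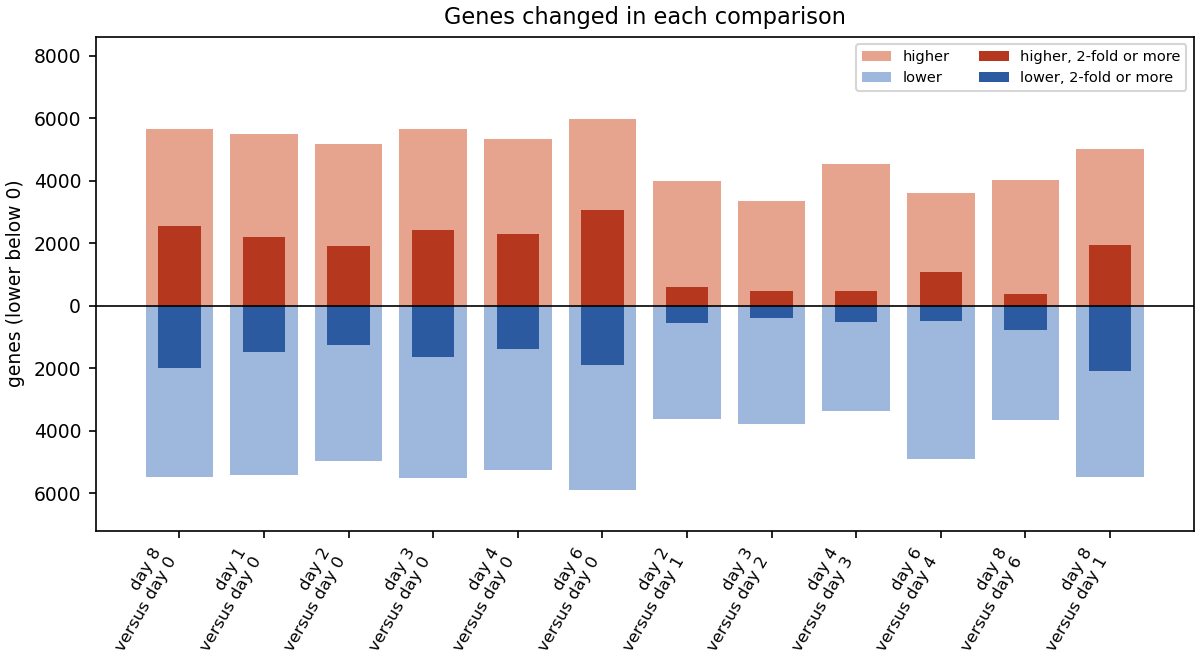
Number of genes called higher (above 0) and lower (below 0) in each comparison with edgeR, with pale bars for all called genes and dark bars for those changed at least 2-fold. Day 8 against day 0 has 5651 higher and 5496 lower genes, of which 2530 and 2000 changed at least 2-fold.

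Sampled days were compared with the sampled day before them to place the changes in time. Time since the medium was renewed may have differed between the days of a step, so a step may not reflect induction alone. From day 1 to day 2 luminal genes were higher in 10 of 17 cases and lower in 1, with a median of 0.61 (adjusted p = 1.7e-05, and 0.0141 with an estimated correlation). Contractile genes were higher in 10 of 14 and lower in 1, with a median of 0.97 (7.68e-26 and 0.000625). Cell cycle genes were lower in 29 of 30 and higher in 1, with a median of -0.52 (9.85e-14 and 0.00113). TXNIP, an inhibitor of thioredoxin, fell by 3.63 ± 0.165, and SFRP5 rose by 3.58 ± 0.174 and VEGFD by 3.45 ± 0.209. In this step 3975 genes were higher and 3634 lower, of which 598 and 547 changed at least 2-fold. From day 2 to day 3 cholesterol synthesis genes were higher in 19 of 20 cases and lower in 0, with a median of 0.71 (1.15e-20 and 0.000625). Cell cycle genes were higher in 24 of 30, with 1 lower and a median of 0.47 (2.02e-11 and 0.00175). Fibroblast genes were lower in 14 of 22 cases and higher in 2 (15 and 2 adjusted over the list alone), with a median of -0.68 (3.07e-14 and 0.00113). Collagen and matrix genes were lower in 17 of 21 and higher in 3, with a median of -0.57 (1.84e-17 and 0.0326). Here TXNIP rose by 4.26 ± 0.155 and DTNA by 3.26 ± 0.198, and C1QL2 fell by 3.51 ± 0.101. In this step 3330 genes were higher and 3786 lower, of which 472 and 401 changed at least 2-fold. The other counts of this paragraph were the same when adjusted over the list alone.

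Basal genes had been higher in 10 of 13 cases and lower in 1 from day 1 to day 2 (11 and 1 adjusted over the list alone), with a median of 0.29 (adjusted p = 0.000226, but adjusted p = 0.14 with an estimated correlation, so the call was lost). From day 2 to day 3 they were higher in 7 and lower in 4 (7 and 5 adjusted over the list alone), with a median of 0.16 (adjusted p = 0.127). From day 3 to day 4 basal genes were higher in 12 of 13 cases and lower in 0, with a median of 0.54 (adjusted p = 1.36e-10, and 0.0296 with an estimated correlation). Junction genes were higher in 18 of 32 cases and lower in 0 (19 and 0 adjusted over the list alone), with a median of 0.42 (0.000271, but adjusted p = 0.0713 with an estimated correlation, so the call was lost). Cell cycle genes were lower in 25 of 30 cases and higher in 1 (26 and 1 adjusted over the list alone), with a median of -0.45 (2.52e-14 and 0.00113). Cholesterol synthesis genes were lower in 18 of 20 and higher in 1, with a median of -0.34 (1.63e-06 and 0.00921). MGP rose by 3.34 ± 0.13 and WNT10A by 3.62 ± 0.508, and CXCL8 fell by 2.37 ± 0.0602 and IL6 by 2.04 ± 0.082. In this step 4528 genes were higher and 3390 lower, of which 476 and 535 changed at least 2-fold. From day 4 to day 6 skin markers were higher in 10 of 12 cases and lower in 1, with a median of 3.59 (2.15e-29 and 0.00032). Basal genes were higher in 7 of 13 cases and lower in 2 (8 and 4 adjusted over the list alone), with a median of 0.26 (2.73e-06, but adjusted p = 0.0782 with an estimated correlation, so the call was lost). Junction genes were higher in 18 of 32 with 3 lower and a median of 0.43 (3.25e-08 and 0.0169). KRT1 went from 3 to 524 counts, a ratio of 169 (95% interval 57.4 to 821), DSC1 rose by 5.63 ± 0.381 and DMKN by 5.20 ± 0.183, and KRT18 fell by 3.40 ± 0.0765 and ESM1 by 3.81 ± 0.113. In this step 3615 genes were higher and 4907 lower, of which 1064 and 487 changed at least 2-fold.

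From day 6 to day 8 skin markers were higher in 11 of 12 cases and lower in 0 (11 and 1 adjusted over the list alone), with a median of 2.27 (adjusted p = 2.43e-33, and 0.00032 with an estimated correlation). Basal genes were higher in 12 of 13 with 0 lower and a median of 0.62 (5.32e-15 and 0.0169). Contractile genes were lower in 11 of 14 cases and higher in 1, with a median of -0.38 (0.000325 and 0.0431). Collagen and matrix genes were lower in 20 of 21 and higher in 0 (20 and 1 adjusted over the list alone), with a median of -0.55 (1.39e-12, but adjusted p = 0.058 with an estimated correlation, so the call was lost). ASPRV1, an epidermal protease, rose by 4.75 ± 0.31, KRT1 by 3.48 ± 0.0947 and KRTDAP by 3.41 ± 0.154, and KRT18 fell by 2.54 ± 0.148, SPP1 by 2.46 ± 0.08 and VGF by 2.55 ± 0.271. In this step 4021 genes were higher and 3651 lower, of which 374 and 784 changed at least 2-fold.

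Day 8 was also compared with day 1, since both were in induction medium. Basal genes were higher in 12 of 13 cases and lower in 0, with a median of 1.55 (adjusted p = 3.25e-27, and 0.00527 with an estimated correlation). Junction genes were higher in 22 of 32 with 3 lower and a median of 1.65 (3.07e-14 and 0.00601). Skin markers were higher in 12 of 12 with a median of 6.15 (8.81e-30 and 0.00032). Luminal genes were higher in 10 of 17 cases and lower in 7, with a median of 2.42 (0.00307 and 0.0431). Fibroblast genes were lower in 16 of 22 and higher in 5, with a median of -1.32 (2.07e-10 and 0.00267). Collagen and matrix genes were lower in 18 of 21 and higher in 2 (19 and 2 adjusted over the list alone), with a median of -1.74 (3.04e-15 and 0.0431). KRT1 was at least 1950-fold and C28H10orf99 at least 529-fold higher, AQP3, a water and glycerol channel, rose by 10.53 ± 0.176, and CXCL8 fell by 7.01 ± 0.0868, ESM1 by 7.91 ± 0.113 and C1QL2 by 8.25 ± 0.174. In all 4998 genes were higher and 5494 lower, of which 1948 and 2085 changed at least 2-fold.

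Calls against day 0 at day 1 and day 8 were compared. Of the 5474 and 5651 genes called higher, 3225 were shared, against 1969 for independent lists, and of the 5428 and 5496 called lower, 3501 were shared, against 1899. In addition, 1704 genes were called in opposite directions. In 20 simulations days 0, 1 and 8 were all drawn from the day 0 means. Days 1 and 8 were each tested against the same simulated day 0. The shared count had a mean of 0 (highest 0) for higher and 0.1 (highest 1) for lower genes. Without changed genes, these simulations cannot show how much of the overlap among changed genes came from sharing day 0. With day 1 set against day 0 replicate 1 and day 8 against day 0 replicate 2, chosen after the data were seen, 2742 higher and 3150 lower genes were shared, against 1721 and 1722 for independent lists. The other way round 2986 and 3121 were shared, against 1775 and 1603. Each of these comparisons had 1 day 0 library, which was assumed to vary like the other libraries. The day 0 pair differed more than the pairs of the other days (chi-square per degree of freedom 8.12, against 1.8 to 4.58). The assumption may therefore understate the spread at day 0.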

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

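Every alternative named here was chosen before the data were examined. Tested against a 1.5-fold change, which asks for more than a difference from 0, genes higher and lower numbered 2878 and 2550 at day 8 against day 0, 2658 and 2079 at day 1, 2083 and 1692 at day 2, 2856 and 2345 at day 3, 2524 and 1847 at day 4 and 3490 and 2699 at day 6. In the steps they numbered 630 and 559 (day 2 against day 1), 326 and 377 (day 3 against day 2), 433 and 674 (day 4 against day 3), 1135 and 539 (day 6 against day 4), 410 and 695 (day 8 against day 6), and 2293 and 2571 for day 8 against day 1. With an estimated correlation, lists called down against day 0 numbered 8 at day 1, 8 at day 2, 5 at day 3 and 7 at day 8. Lists called up numbered 2 at each of days 2, 3 and 4. Some lists lost their call with an estimate under the preset 0.01: interferon at day 1 (-0.043), leukocyte at day 2 (-0.08) and fibroblast at day 3 (-0.037). These values argue against a higher correlation within those lists as the cause of their loss. Others had a higher estimate, such as collagens and matrix at day 1 (0.278). The cause was not tested further. With fry, which does not compare a list with other genes, lists called up numbered 7, 8, 7, 10, 11 and 14 at days 1, 2, 3, 4, 6 and 8, and lists called down 20 at day 1, 21 at day 3, 16 at day 4 and 17 at day 6. Among genes changed at least 2-fold, 79 terms were over-represented in higher and 90 in lower genes, against 26 and 46, and the cause was not tested. The first principal component of all tested genes held 47.6% of the variance, against 65.8%. Counts of genes stayed within 1.5 times under DESeq2, DESeq2 size factors, both filters and the fit of the compared days alone. No called result reversed, but some uncalled ones changed sign. The balance of higher and lower genes depended on the scaling. With DESeq2 size factors the share of called genes that were higher went from 42.4% to 49.5% for day 6 against day 4. It went from 57.2% to 52.7% for day 4 against day 3, and from 47.6% to 51.1% for day 8 against day 1. For day 4 against day 0 it went from 50.3% to 46.4%, and for day 8 against day 0 from 50.7% to 51.3%. Without 1 library, where the lone library left is assumed to vary like the others, day 8 against day 0 had 5080 to 5845 higher and 4953 to 5489 lower genes, the all-days count was 14312 to 14450, and 15885 of 16044 named-gene results kept their side of the threshold and direction. Of 1146 named-gene results, 15 lost and 1 gained a call with DESeq2, and 12 and 1 in the fit of the compared days alone. With genes at 0 counts set to their bound, the skin list median at day 2 was -0.88, not -1.43, and the adipocyte list median at day 1 turned from 0.08 to -0.04. Replicate numbers did not pair the libraries: over 21 pairs of days, deviations of same-numbered libraries correlated at -0.19 to 0.11 over 12662 genes. With the replicate block, the counts of genes changed, day 8 versus day 0, higher, and genes changed, day 8 versus day 0, lower, were 5592 and 5431. Having 2 libraries per day and the depth limit what was detectable for genes near 3 counts per library.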

Other observations

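The tests of carry-over, of outgrowth, of actin paralogs, of a single contractile population and of the ZBTB16 fold were chosen only after the result was seen, and those of keratin paralogs and of a glucocorticoid before. The carry-over test was given its minimum of 20 counts at day 0, and the outgrowth test was replaced by its present form, which follows genes that fell at day 1, after outcomes of earlier forms were seen.

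PRLR and PDK4 were outside the rule for named genes and were chosen after their values were seen. PRLR, the prolactin receptor, was at 0.1863 ± 0.0646 CPM at day 0 (SD, n = 2), 6.461 ± 1.17 CPM at day 6 and 8.575 ± 0.499 CPM at day 8, a log2 fold change of 5.48 ± 0.369 (SE; edgeR adjusted p = 2.5e-12), while casein transcripts stayed at or near 0 counts. AQP3 went from 1.026 ± 0.205 CPM at day 0 to 11.57 ± 0.507 CPM at day 4 and 745.8 ± 28.2 CPM at day 8. PDK4, a kinase that restrains pyruvate oxidation and 1 of the glucocorticoid-induced genes listed before their values were seen, rose by 9.07 by day 8. Its level at day 0 was 0.303 CPM, which leaves the fold uncertain. LOC102190288, described as a UDP-glucuronosyltransferase 1-1, rose by 8.51 ± 0.185, beside the terms for retinol and drug metabolism.

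Epithelial transcripts were present at day 0 and basal keratins were higher at day 8. Carry-over of reads from day 8 into day 0 libraries cannot account for the day 0 level: AQP3 at day 0 was 0.138% of its day 8 level, which limits carry-over to 34.9 CPM of KRT5 against 3810 CPM measured. Reads moved among keratin paralogs alone would leave the keratin total flat, but the summed CPM of 61 keratin genes rose 4.62-fold, from 12960 to 59900. The sum cannot show which of several near-identical keratins rose, so sharing among them stays open for KRT5, KRT6A and KRT14 singly. Where all cells keep their expression, outgrowth of 1 epithelial population takes genes that fell at day 1 in 1 direction by day 8. Of 12 basal genes lower at day 1, 3 were lower and 8 higher at day 8. Of 23 junction genes 7 were lower and 15 higher. Each of 20 alternative fits had at least 3 and 8 basal genes, and at least 7 and 14 junction genes. These values argue against outgrowth only if the epithelial and the other cells both kept their expression. Outgrowth beside other cells that changed their expression stays open. Growth of several kinds of epithelial cells, growth after a change of expression (from day 1 to day 8, 12 of 13 basal genes were higher and 0 lower, but from day 2 to day 3, 7 were higher and 4 lower), a change of expression without growth, and the day of induction itself may each explain the rise and were not separated here.

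Contractile genes were higher while TGF-beta responsive genes were lower. Reads shared among actin paralogs may raise single actins, but 10 of 12 contractile members other than actins were higher at day 8. Where all cells keep their expression, a changing share of 1 contractile cell population would move its genes together. Of 12 members higher at day 4, 4 rose again and 6 fell from day 4 to day 6. That argues against a changing share only if the other cells kept their expression too. The day of induction stays open, and so does a change within the contractile cells or within the other cells.

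ZBTB16 was among the leading genes from day 1. A fold inflated by a day 0 level near 0 had no separate test, since the bound of at least 120-fold (370 counts at day 1 against 0) is what put the gene among the leading ones, and its true fold is not known. A glucocorticoid acting in the induction medium is a hypothesis: of 10 glucocorticoid-induced genes listed before their values were seen, 7 were higher at day 1, just at the bound set in advance, among them FKBP5 (114 against 57.4 CPM), PER1 (28.1 against 9.93 CPM) and TSC22D3 (20.8 against 8.62 CPM), while GLUL was lower and ERRFI1 and CRISPLD2 were not called. At day 8, 5 of the 10 were higher and 4 lower, namely FKBP5 (46.8 CPM), GLUL, ERRFI1 and CRISPLD2, which fell by 0.30, 0.41, 1.08 and 1.14 on the log2 scale. What the medium contains is not given in the sources used here, and other differences between day 0 and day 1 remain open.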
